A study of Mus musculus with 12 samples.

How the data were processed

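RNA from the oviduct and the uterus of pregnant mice was measured on 12 one-colour Affymetrix arrays. Per the labels' protocols, the females were 9 to 11 weeks old, were mated with wild-type males and were sampled at gestational day 6, and only implantation sites of the uterus were taken, without the mesometrium. Control females carried floxed Smad4 alleles, and mutant females carried the same alleles with a cre recombinase expressed from the Amhr2 locus. No group carried the cre without floxed alleles, so effects of Smad4 loss and of the cre at the Amhr2 locus cannot be told apart. Per the labels' protocols, 250 ng of total RNA was labelled with whole-transcript kits. The RNA kit differed between the tissues (PicoPure for oviduct, RNeasy Plus Mini for uterus), so tissue and RNA kit cannot be told apart. The submitters' processing notes name the oligo package, with no version. The background correction, the normalization and the genome build are not given in the sources used here.

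The deposited values are a normalized score per probe set on a scale whose log base, if any, is not given in the sources used here. They ran from -0.736 to 4.00, with array medians of 0.299 to 0.358, standard deviations of 0.712 to 0.730, and a background peak between -0.0860 and -0.0661. A difference is therefore given in deposited units and never as a fold. Each array's percentile scale is given for orientation. The arrays were not quantile-normalized as deposited, and the values were tested as they stand. The design had been written for log2 values. The planned limits on fold were therefore not applied, and limits of 0.2 and 0.3 on the difference were used in their place, chosen after the data had been seen.

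Of 25429 probe sets, 24675 had exactly 1 gene symbol in the platform annotation, 0 had several and 754 were not listed there and are unnamed here. All 24675 symbols matched a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other, and 0 symbols changed. Each gene had 1 probe set, so taking the probe set with the highest mean per gene, which had been intended, alters nothing. Detection calls were not used here.

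Samples were grouped by title and strain, with 3 arrays in each of 4 groups. The description field reads the same for mutant and control samples and was not used. The labels do not say that each array came from a separate animal, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

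Genes above the array's 40th percentile on at least 3 of the arrays fitted were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The oviduct and the uterus were fitted separately. The difference of the mutant effect between tissues, and the control tissues against each other, came from 1 fit of all 12 arrays. All adjusted p-values for single genes are limma's. Every SE is that of a limma fit, unless said to be over members. For mast cell markers not past the threshold it is that of the fit with no filter. Every SD given after a group mean is over 3 arrays.

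Before the data were examined, 34 gene lists were fixed (737 distinct symbols, of which 690 had a probe set). Lists with at least 5 tested genes were tested with limma's camera at a preset correlation between genes of 0.01, and again with a correlation estimated per list. List members were also counted adjusted over the list alone. Some genes stand in more than 1 list. The tests, the groups, the lists, the alternatives and the rule for named genes were also set before the data were examined. The rule takes, for the mutant comparisons and their difference, the 12 genes with the largest difference in each direction among those past the threshold, whose mutant and control values also do not overlap in the comparisons within a tissue. Where fewer than 12 pass, all are taken, and where fewer than 5 of a direction pass, the first 5 by unadjusted p are added. For the control tissues it takes the 6 largest in each direction. It adds Smad4, Amhr2, up to 4 members of each list with the smallest p, and list members needed as markers of another cell type. Predicted genes with no informative name may be left out.

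Alternatives were no filter, a stricter filter at the 60th percentile, quantile normalization, median centring, all 12 arrays in 1 fit, the replicate number as a block, array weights, a trended and robust prior variance, and leaving out each array in turn. Tests of unnamed probe sets together with the named ones, and of the difference between tissues over only the genes that pass the filter in both, were added after the data had been seen. Background here means a value at or below an array's 40th percentile.

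The fits were tested on simulated data with known shifts. In the simulated oviduct comparison of 14902 genes, 54.5% of genes shifted by 0.2 and 96.9% of those shifted by 0.4 were recovered. In the simulated uterus comparison of 14903 genes, the shares were 46.2% and 90.8%. In the simulated difference between tissues, over 16154 genes, they were 43.1% and 82.1%. The noise was drawn independently for each gene. The simulated oviduct had 174 calls in all, where the data had 18, so its shares overstate how often such shifts would pass there. Figures were drawn with matplotlib 3.10.9.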

Results

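Gene expression was compared between control females with floxed Smad4 alleles and mutant females in which cre recombinase, expressed from the Amhr2 locus, acts on those alleles. Smad4 is the common mediator of TGF-beta and BMP signalling, and Amhr2 encodes the receptor for anti-Mullerian hormone. Oviduct and uterine implantation sites were taken at gestational day 6, when the uterine stroma decidualizes, with 3 arrays per tissue and genotype. Across all probe sets, arrays of one group correlated at r = 0.992 to 0.994, arrays of one tissue but different genotype at 0.990 to 0.993, and arrays of different tissues at 0.882 to 0.902. Values are in deposited units, whose scale is not stated, so differences are not folds.

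The targeted gene was examined first. In the uterus Smad4 was 2.12 ± 0.0213 (SD, n = 3) in controls and 1.93 ± 0.0611 (SD, n = 3) in mutants, and it fell by 0.187 (SE 0.0369, adjusted p = 0.0373). In the oviduct it was 2.20 ± 0.0472 (SD, n = 3) in controls and 2.05 ± 0.0701 (SD, n = 3) in mutants, a difference of -0.156 (SE 0.0429) that did not pass the threshold (adjusted p = 0.408). All 3 mutant arrays lay below all 3 control arrays in each tissue. The mutant effect on Smad4 did not differ detectably between tissues (difference -0.0310, SE 0.0583, adjusted p = 0.881). The uterine call was lost without control array 1 (adjusted p = 0.0955), control array 2 (0.128), control array 3 (0.139), mutant array 1 (0.116) or mutant array 2 (0.124). The floxed deletion removes part of the gene, and only in cells that express the cre, so a probe set over the whole gene in whole tissue is a limited check of the labels. Amhr2, whose locus carries the cre, fell by 0.258 in the uterus (SE 0.0461, adjusted p = 0.0242), from 0.257 ± 0.0575 to -0.00164 ± 0.0765 (SD, n = 3 each), at background on every mutant array. That call was lost without mutant array 1 (adjusted p = 0.0633) or mutant array 2 (0.0674). In the oviduct Amhr2 was at background in both genotypes, -0.0307 in controls and -0.0890 in mutants, and was not tested.

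In the mutant uterus, 12 of 35 decidualization genes and 5 of 14 BMP response genes fell, while 5 of 20 natural killer cell genes rose, together with Apod and Gjb2. The list tests follow the single genes. The prolactin family genes Prl6a1, Prl3c1, Prl8a2 and Prl8a9 fell by 0.950 (SE 0.0479), 0.832 (SE 0.0823), 0.798 (SE 0.0781) and 0.745 (SE 0.0423), and Prl8a9 lay at background on every mutant array. Prl8a2, which encodes a decidual prolactin-related protein, went from 3.01 ± 0.0523 in controls, the 99.8th percentile of the array, to 2.21 ± 0.180 in mutants (SD, n = 3 each). Serpinb9e, a serine protease inhibitor gene, fell by 1.11 (SE 0.0448, adjusted p = 3.6e-05), from 1.41 ± 0.0691 to 0.299 ± 0.0601 (SD, n = 3 each). Hsd3b6, a hydroxysteroid dehydrogenase gene, fell by 1.02 (SE 0.145, adjusted p = 0.00912). Erv3 fell by 0.721, the transmembrane mucin gene Muc13 by 0.698, Nccrp1 by 0.612, the dopamine receptor gene Drd4 by 0.577 and the hepcidin gene Hamp by 0.566. Ighv14-3, an immunoglobulin variable gene, fell by 0.602 (SE 0.120, adjusted p = 0.0398), a call lost without control array 2 (adjusted p = 0.0705) or any one of mutant arrays 1, 2 and 3 (0.117, 0.0964 and 0.0708), with all 12 arrays in 1 fit (0.319) and with a trended and robust prior variance (0.17). That of Hsd3b6 was lost with the trended prior (adjusted p = 0.117) and without control array 1 (0.0513).

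Of the genes that rose in the mutant uterus, Apod, which encodes a lipid-binding protein, differed by 0.772 (SE 0.0554, adjusted p = 0.000906), from 0.714 ± 0.0579 to 1.49 ± 0.109 (SD, n = 3 each). Gjb2, a gap junction gene, was higher by 0.586 (SE 0.0803). Crct1, Asprv1 and Sprr1a, known from the cornified layer of skin, were higher by 0.550, 0.487 and 0.470. The thioesterase gene Them5 was higher by 0.544 and Acod1, which encodes the enzyme that makes itaconate, by 0.513. The small nucleolar RNAs Snord12, Snord53 and Snord72 were higher by 0.553, 0.543 and 0.501, and the pseudogene Psmb5-ps by 0.436. Without control array 3 the calls of Acod1, Sprr1a, Snord12, Snord53 and Psmb5-ps were lost (adjusted p = 0.0689, 0.125, 0.0893, 0.0681 and 0.0599). Those of Acod1, Sprr1a and Snord12 were lost without control array 1 (0.109, 0.153 and 0.0847), and those of Acod1, Sprr1a and Snord53 without control array 2 (0.103, 0.143 and 0.0533). Snord12 also lost its call without mutant array 1 (0.0626) and Sprr1a without mutant array 2 (0.0711). With the trended prior the calls of Acod1, Sprr1a, Snord12 and Snord53 were lost (adjusted p = 0.0939, 0.118, 0.113 and 0.0864), and with quantile normalization that of Sprr1a (0.0568).

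**Figure D1:**
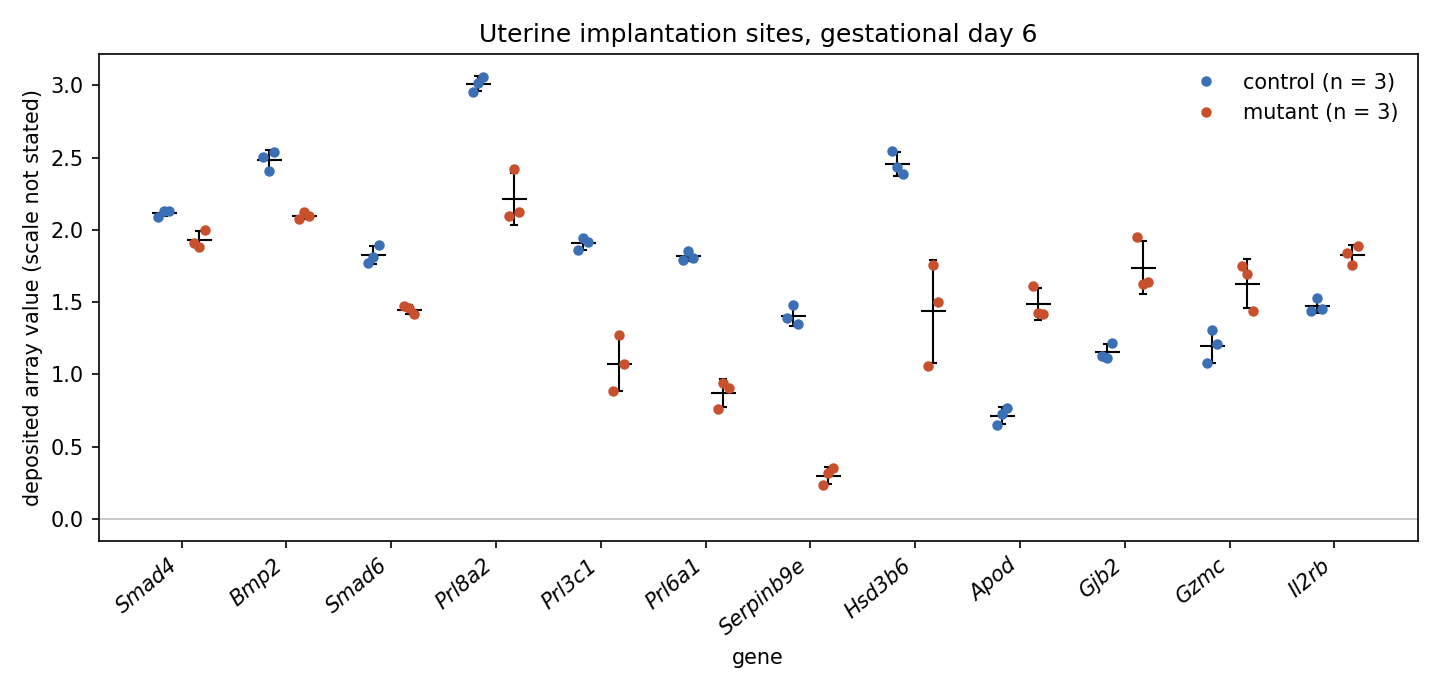
Deposited array values (y axis, scale not stated) of 12 genes (x axis) in uterine implantation sites. Each coloured point is 1 array (n = 3 per genotype), and the black line and bars are the mean ± SD. The mutant arrays of Prl8a2 average 2.21 against 3.01 in controls, and those of Apod 1.49 against 0.714.

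Among the fixed lists, 12 of the 35 tested decidualization genes fell and 1, Gjb2, rose. Adjusted over the list alone, 20 were lower and 2 higher. The bone morphogenetic protein gene Bmp2, needed for decidualization, fell by 0.386 (SE 0.0390, adjusted p = 0.00311). The list's median difference was -0.129, and camera called it lower (adjusted p = 2.6e-13), a call lost with an estimated correlation (adjusted p = 0.143). Of 14 BMP response genes, 5 fell and 0 rose, and 6 were lower adjusted over the list alone. Atoh8, the inhibitory Smad gene Smad6, Smad9 and the transcriptional inhibitor gene Id1 fell by 0.446, 0.377, 0.308 and 0.191. The call of Id1 was lost without control array 1 (adjusted p = 0.0638) or control array 3 (0.0675). The list was called lower (median -0.113, adjusted p = 4.03e-07; adjusted p = 0.143 with an estimated correlation). Among TGF-beta family ligands and receptors, 5 of 33 fell and 1, Bmp7, rose by 0.298 (SE 0.0350, adjusted p = 0.00444). The list also holds Smad4 and Amhr2, so those that fell include the floxed gene and the gene whose locus carries the cre. Bmp8a was among those that fell, by 0.345, a call lost without control array 3 (adjusted p = 0.0536). The list as a whole was not called (adjusted p = 0.11). Of 16 TGF-beta response genes, 0 fell and 1, Pmepa1, rose past the threshold. That list had a median of -0.0362, with 5 differences positive and 11 negative, and camera did not call it (adjusted p = 0.278).

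All 20 tested genes of uterine natural killer cells had positive differences in the mutant uterus, and 5 of them rose. Adjusted over the list alone, 13 were higher and 0 lower. Il2rb, a cytokine receptor subunit, was higher by 0.356 (SE 0.0420), the granzyme gene Gzmc by 0.430 (SE 0.0840), the lectin-like receptor gene Klrd1 by 0.30 and Ctsw, a cathepsin gene, by 0.238. The calls of Gzmc, Klrd1 and Ctsw were lost without control array 1 (adjusted p = 0.131, 0.0838 and 0.14), control array 3 (0.12, 0.0885 and 0.141) or mutant array 1 (0.103, 0.0609 and 0.0962). That of Gzmc was also lost without control array 2 (adjusted p = 0.0515) or mutant array 2 (0.11) and with the trended prior (0.113), and that of Ctsw without mutant array 3 (0.075). The list was called higher (median 0.185, adjusted p = 5.59e-11; adjusted p = 0.143 with an estimated correlation). By median, the other cell type lists differed less. The neutrophil list had a median of 0.0702, with 8 of 9 genes positive, 1 rising past the threshold and 1 falling. The 1 that rose was Hdc, by 0.355 (adjusted p = 0.0271), which also stands among the mast cell markers used below. Camera did not call it (adjusted p = 0.0591). The smooth muscle list had a median of -0.0321 and 0 of 27 genes past the threshold, and the macrophage list -0.0092 and 0 of 18. The blood endothelium list was called lower with a median of -0.0348 and 0 of 29 genes past the threshold (adjusted p = 0.0212; adjusted p = 0.774 with an estimated correlation). That call was lost without control array 1 (adjusted p = 0.0626), control array 3 (0.069) or mutant array 2 (0.0544).

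Smaller lists were also called lower in the mutant uterus. Among genes of the ovarian follicle and corpus luteum, 2 of 11 fell, namely the steroid-producing enzyme gene Cyp11a1 by 0.274 and Parm1 by 0.220 (list adjusted p = 0.0139; adjusted p = 0.512 with an estimated correlation and 0.111 with no filter on dim genes). The call of Parm1 was lost without control array 1 (adjusted p = 0.0965), control array 3 (0.0976), mutant array 1 (0.0731) or mutant array 2 (0.0729), and that of Cyp11a1 without control array 3 (0.0511). Among uterine gland genes, 1 of 12 fell, Spink1, a protease inhibitor gene, by 0.352 (list adjusted p = 0.0216; adjusted p = 0.774 with an estimated correlation). That list's call was lost without control array 1 (adjusted p = 0.202) or mutant array 1 (0.093) and with the stricter filter on dim genes (0.058). The call of Spink1 was lost without any one of control arrays 1, 2 and 3 (adjusted p = 0.137, 0.123 and 0.0542), without mutant array 1 (0.0892) or mutant array 2 (0.0851), and with the trended prior (0.0861). Among adipocyte genes, 1 of 7 fell, Retn, by 0.326 (list adjusted p = 0.00211; adjusted p = 0.61 with an estimated correlation). Wnt signalling genes went both ways: 4 of 34 fell, with Sfrp5 by 0.395 and Notum, an inhibitor of Wnt ligands, by 0.325, and 2 rose, Wnt16 by 0.349 and Nkd2 by 0.264. Of 10 Hedgehog signalling genes, Ptch1 and Gli1, both targets of the pathway, rose by 0.219 and 0.30. Both calls were lost without control array 1 (adjusted p = 0.0701 and 0.0947) or control array 3 (0.0712 and 0.054), that of Ptch1 without mutant array 1 (0.0527) and that of Gli1 without control array 2 (0.0847). Of 37 cell cycle genes, the ribonucleotide reductase genes Rrm2 and Rrm1 fell by 0.324 and 0.225, and 0 rose past the threshold. The list leaned the other way, with 27 of the 37 differences positive and a median of 0.0219. The call of Rrm1 was lost without control array 1 (adjusted p = 0.0819), control array 3 (0.0712) or mutant array 2 (0.0592). Among progesterone-responsive genes 2 of 21 rose, Acod1 and Cyp26a1 (by 0.268), and 3 fell. Neither the Wnt, Hedgehog, cell cycle nor progesterone list was called.

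Over all 14910 genes tested in the uterus, 98 rose and 258 fell, 356 in all, and 2184 had an unadjusted p under 0.05. The groups did not overlap for 20.8% of genes, where chance gives 10%. The count was 155 without control array 1, 210 without control array 2, 124 without control array 3 and 208 without mutant array 1.

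In the oviduct 11 genes were higher and 7 lower in mutants, of 14891 tested. Cpa3, a carboxypeptidase of mast cell granules, was higher by 0.637 (SE 0.0543, adjusted p = 0.00889), at 0.480 ± 0.121 in controls and 1.12 ± 0.0130 in mutants (SD, n = 3 each). The mast cell protease genes Mcpt4 and Tpsb2 were higher by 0.325 (SE 0.0441) and 0.326 (SE 0.0381), and Rgs13, a regulator of G protein signalling, by 0.302 (SE 0.0426). The extracellular matrix genes Cilp and Tnc were higher by 0.598 (SE 0.0559, adjusted p = 0.00889) and 0.355 (SE 0.0394), and Pi16, a peptidase inhibitor gene, by 0.544 (SE 0.0581). Psmb5-ps was higher by 0.382, the calcium-binding protein gene Necab1 by 0.332, the pentraxin gene Nptx2 by 0.304 and Apod by 0.256. Tpsb2, Rgs13 and Necab1 lay at background on every control array, with means of -0.0491, -0.00386 and -0.0213. Without control array 1 the calls of Mcpt4, Tnc, Nptx2 and Apod were lost (adjusted p = 0.115, 0.058, 0.122 and 0.115), without control array 2 those of Mcpt4, Tpsb2, Rgs13, Tnc, Nptx2 and Apod (0.0998, 0.0651, 0.117, 0.0575, 0.0933 and 0.116), and without mutant array 3 those of Nptx2 and Apod (0.0834 and 0.0657). With quantile normalization the calls of Mcpt4, Rgs13, Nptx2 and Apod were lost (adjusted p = 0.0566, 0.0541, 0.0566 and 0.0661), and with all 12 arrays in 1 fit those of Mcpt4 and Apod (0.075 and 0.0638).

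The oviduct genes that fell were 3 immunoglobulin variable genes and 4 others. Ighv9-1, Ighv7-1 and Ighv2-9-1 fell by 0.775, 0.753 and 0.559, calls lost with all 12 arrays in 1 fit (adjusted p = 0.191, 0.168 and 0.0638). Ighv9-1 lay at background on every mutant array. Sfrp4, a secreted antagonist of Wnt ligands, fell by 0.313 (SE 0.0358, adjusted p = 0.0144), from 0.926 ± 0.0545 to 0.613 ± 0.0189 (SD, n = 3 each). Cacng4, an ion channel subunit gene, fell by 0.281, Astn1 by 0.239 and Cpz, a secreted carboxypeptidase gene, by 0.230. The call of Cpz was also lost with all 12 arrays in 1 fit (adjusted p = 0.0894). Without control array 1 the calls of Sfrp4, Cacng4, Astn1 and Cpz were lost (adjusted p = 0.058, 0.101, 0.115 and 0.115), without control array 2 those of Cacng4, Astn1 and Cpz (0.0651, 0.12 and 0.0964), and without mutant array 3 those of Sfrp4 and Cpz (0.0532 and 0.0562). The 18 calls stood beside 1099 genes with an unadjusted p under 0.05, and groups did not overlap for 12.7% of genes, where chance gives 10%. The limma count fell to 0 without mutant array 1 (893 genes at an unadjusted p under 0.05), 2 without control array 3 (Cpa3 and Cilp) and 6 without mutant array 2. With quantile normalization 7 genes were higher and 7 lower.

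**Figure D2:**
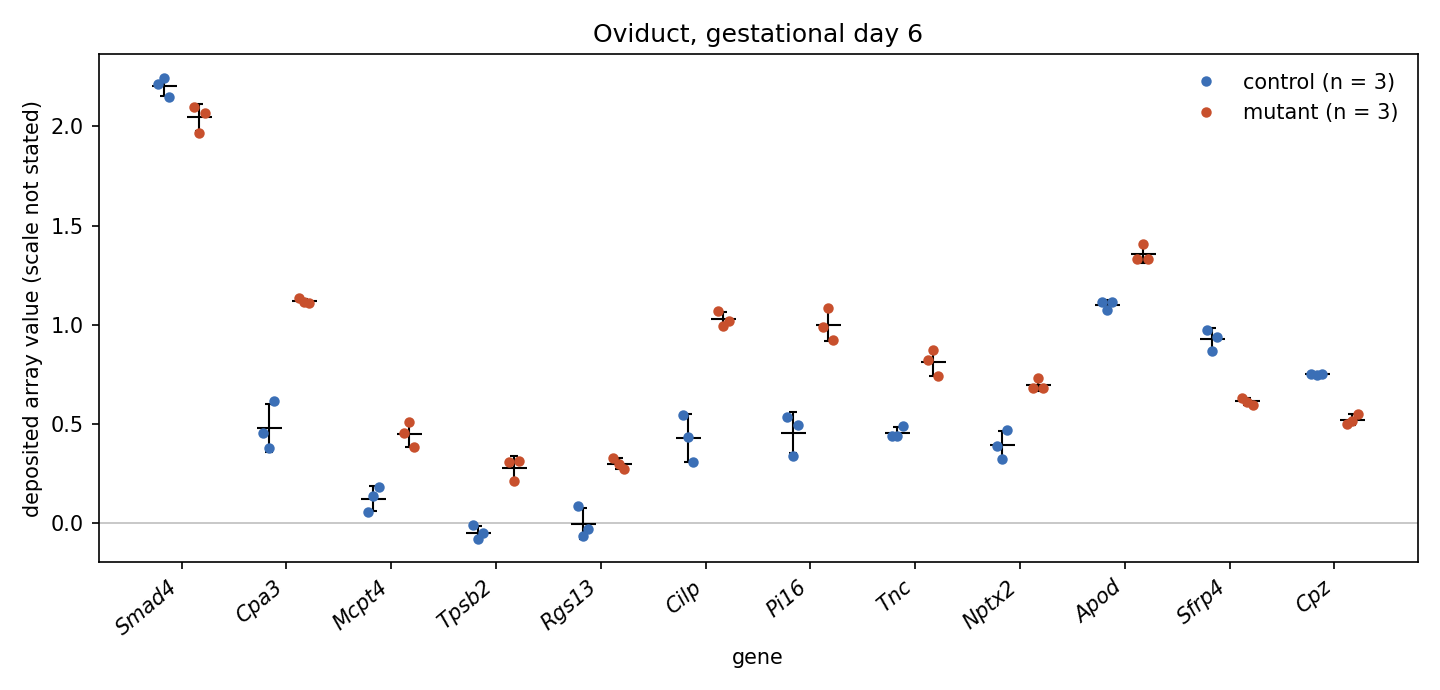
Deposited array values (y axis, scale not stated) of 12 genes (x axis) in the oviduct. Each coloured point is 1 array (n = 3 per genotype), and the black line and bars are the mean ± SD. Cpa3 averages 1.12 in mutants against 0.480 in controls, and Sfrp4 0.613 against 0.926.

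The camera test called 6 of 31 lists in the oviduct, all higher in mutants, and 0 of them with an estimated correlation. Extracellular matrix genes had a median difference of 0.0323, and 2 of 34 rose, Cilp and Tnc (6 higher adjusted over the list alone). Smooth muscle genes had a median of 0.0362 and epithelial genes of 0.0309, with 0 of 26 and 0 of 23 past the threshold. TGF-beta response genes had a median of 0.0124 with 1 of 16 past it, Tnc, which the matrix list also holds. Interferon response genes had a median of 0.0496 with 0 of 21 past it, and adipocyte genes a median of 0.123 with 0 of 9 past it. The adipocyte call was lost with the stricter filter on dim genes, where the median was 0.0288 (adjusted p = 0.107). With an estimated correlation the interferon list had an adjusted p = 0.692 and the other 5 lists an adjusted p = 0.684. Without mutant array 2 the adjusted p was 0.166 for the matrix list, 0.106 for smooth muscle and 0.133 for TGF-beta response. The epithelial call was lost without control array 1 (adjusted p = 0.0646) or mutant array 1 (0.0801), and the interferon call without control array 2 (0.0502), control array 3 (0.129) or mutant array 3 (0.583), where its median was -0.0140. The BMP response list was not called in the oviduct (median 0.0079, 0 of 14 past the threshold), nor was the ciliated cell list (median -0.0235, 0 of 38).

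**Figure D3:**
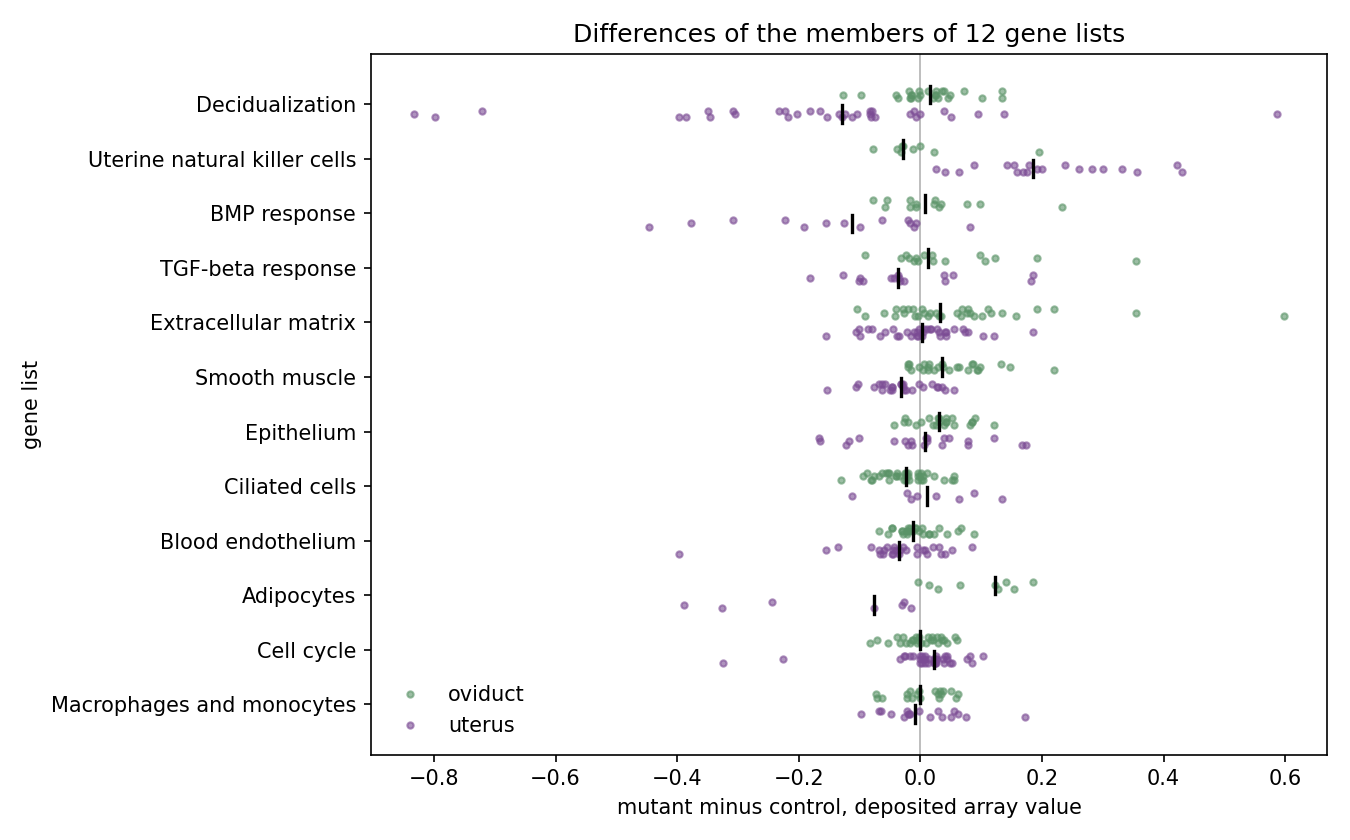
Mutant minus control difference in deposited array value (x axis) of each tested member of 12 gene lists (y axis), in oviduct (green) and uterus (purple). Each point is 1 gene and each black bar the list's median. The decidualization median is -0.129 over 35 genes in the uterus and 0.0165 over 26 in the oviduct, and the natural killer median 0.185 over 20 genes and -0.0284 over 9.

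Whether the mutant effect differed between tissues was tested directly. Of 16182 genes, 262 passed, 65 with a more positive effect in the uterus and 197 with a more negative one, and 2030 had an unadjusted p under 0.05. Of the 262, 69 did not pass the filter in the oviduct, so that no oviduct effect could be measured and the test restates the uterine difference. Over the 13739 genes that passed it in both tissues, 182 were called, 50 more positive and 132 more negative. With the replicate number within genotype as a block, 163 genes were called, and 89 of the 13739. The more negative effects included Serpinb9e (-1.03, SE 0.0626), Prl6a1 (-0.938, SE 0.0632), Prl3c1 (-0.881, SE 0.0980) and Bmp2 (-0.431, SE 0.0480). The more positive ones included Gjb2 (0.589, SE 0.108), Apod (0.516, SE 0.0686) and Klrg1, a receptor gene of natural killer and T cells (0.409, SE 0.0495). Of these, Serpinb9e, Prl6a1, Prl3c1 and Klrg1 lay at background on every oviduct array. Apod was higher in mutants in both tissues, by 0.772 in the uterus and 0.256 in the oviduct. The decidualization list was called more negative in the uterus (10 of 35 genes more negative and 1 more positive) and the natural killer list more positive (2 of 20 more positive). With an estimated correlation the adjusted p was 0.0292 and 0.0446, and with the block as well it was 0.0947 and 0.219. Only 26 of the decidualization genes and 9 of the natural killer genes passed the filter in both tissues. Over these the decidualization call held with an estimated correlation (adjusted p = 0.0298) but was lost with the block as well (0.0928). The natural killer call was lost with an estimated correlation alone (adjusted p = 0.237). Of the other 7 lists called, all more negative in the uterus, none held with an estimated correlation over all genes tested. The BMP response list came nearest (adjusted p = 0.0518, or 0.219 with the block). Over its 13 genes that passed the filter in both tissues the adjusted p was 0.0298, or 0.274 with the block. The adipocyte list, positive in the oviduct and negative in the uterus, had a median of -0.186 (adjusted p = 0.163 with an estimated correlation). The count of genes was 174 without oviduct mutant array 1 and 156 without uterus mutant array 1.

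Across 13739 genes tested in both tissues, the mutant differences correlated at Pearson's r = 0.0754 and Spearman's rho = -0.0388. This is a correlation across genes, which are not independent replicates. It was 0.0204 without oviduct mutant array 2, 0.0204 without uterus control array 1 and 0.118 without uterus control array 3. Apod and Psmb5-ps passed the threshold in both tissues, each higher in mutants, where independent lists would share 0.309 genes. Of 265 uterine calls tested in both, 124 had the same sign in the oviduct, and of 16 oviduct calls 14 had the same sign in the uterus.

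The control tissues differed at 11243 of 16182 genes, 6273 higher in the uterus and 4970 higher in the oviduct. The decidual genes Prl8a2 and Tdo2 were higher in the uterus by 3.20 (SE 0.0662) and 2.93 (SE 0.0516), as were the gland protease genes Prss29 and Prss28 by 2.99 and 2.89, Serpinb9b by 2.69 and Hsd3b6 by 2.68. Ovgp1, which encodes the oviductal glycoprotein, was 3.75 ± 0.0503 in oviduct and 0.765 ± 0.107 in uterus (SD, n = 3 each), a difference of -2.99 (SE 0.0727). A2ml1, Stoml3, Upk1a, the cilium gene Sntn and Cyp2f2 differed by -2.89, -2.86, -2.80, -2.78 and -2.77. Prl8a2, Tdo2, Prss29, Prss28, Serpinb9b and Hsd3b6 lay at background on every oviduct control array, and Stoml3 and Sntn on every uterine one. All 38 ciliated cell genes were lower in the uterus and all 37 cell cycle genes higher, with medians of -1.34 and 1.17. Only 8 of the 38 ciliated cell genes passed the filter in the uterus, so background limits the size of that difference. The camera test also called epithelial, oviduct secretory and mesothelial genes lower in the uterus and matrix, decidualization, natural killer and blood endothelial genes higher. With an estimated correlation none of the 9 calls held, and the lowest adjusted p was 0.099. Tissue and RNA kit cannot be told apart in this comparison.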

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

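The tests of normalization and of the share of decidual stroma, and those over genes that pass the filter in both tissues, were chosen after the result was seen, and the counts over other splits were set beforehand. The mutant effect differed between tissues by the direct test for each of the following genes, given as the uterine effect minus the oviduct effect. The difference was -1.05 for Hsd3b6, -1.03 for Serpinb9e, -0.938 for Prl6a1, -0.881 for Prl3c1, -0.794 for Prl8a2, -0.747 for Erv3 and -0.664 for Prl8a9. It was -0.692 for the sulfotransferase gene Sult1d1, -0.676 for Muc13, -0.674 for Prg4, -0.622 for Hamp and -0.622 for the pacemaker channel gene Hcn4. It was 0.589 for Gjb2, 0.559 for Snord53, 0.530 for Crct1, 0.520 for Snord12, 0.516 for Apod and 0.503 for Them5. It was 0.440 for Cldn1, 0.434 for Cd244a, 0.427 for Asprv1, 0.409 for Klrg1 and 0.404 for Cyp1b1. Prg4, which encodes a lubricating proteoglycan, had a difference of 0.321 in the oviduct and -0.354 in the uterus. Cldn1 (-0.186 in the oviduct and 0.254 in the uterus) and Cd244a (-0.211 and 0.223) also went in opposite directions. Sult1d1 moved more in the oviduct, from 0.842 in controls to 1.407 in mutants, than in the uterus, from 1.777 to 1.65. None of these passed the threshold in the oviduct comparison. The call of Snord12 was lost without most single arrays. Hsd3b6, Serpinb9e, Prl6a1, Prl3c1, Prl8a2, Erv3, Prl8a9, Muc13, Hamp, Crct1, Asprv1 and Klrg1 lay at background on every oviduct array, so their difference restates the uterine effect, and Prg4 did so on the oviduct controls. The decidualization list's median effect differed by -0.131 and the natural killer list's by 0.214. Over the 26 and 9 members that passed the filter in both tissues, the medians were -0.0916 and 0.229, and the natural killer call was lost with an estimated correlation (adjusted p = 0.237). Both list calls were lost with the replicate number within genotype as a block and an estimated correlation (adjusted p = 0.0947 and 0.219). In the uterus, 16 of 492 unnamed probe sets passed the threshold, 2 higher and 14 lower, a signal in probe sets that the comparisons leave out.

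In other splits of the same arrays, relabelling genotype within the tissues was run for 100 of 200 possible relabellings. Only the real one, 1 of 100, gave as many as 262 genes, and the highest other gave 220. The median of the others was 0, and 15 of them gave any call. A relabelling can keep the real uterine split and change only the oviduct one, so a uterine effect alone can set these counts. The relabelling therefore does not decide whether the mutant effect differs between tissues. Each tissue was relabelled on its own, so any pairing of arrays across tissues was not kept. Within each tissue and between control tissues, 3 arrays against 3 make only 10 splits, too few for a share under 0.05. The real uterus split gave 356 genes and the highest other 0, the real oviduct split gave 18 and the highest other 1, and the control tissues gave 11243 and the highest other 0. In each, 1 of 10 splits, the real one, gave as many.

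In the mutant uterus 12 of 35 decidualization genes were lower and 1 higher, and 5 of 20 natural killer genes were higher, with both list calls lost with an estimated correlation (adjusted p = 0.143 each). With quantile normalization all 12 of the decidualization genes past the threshold remained lower past it and all 5 of the natural killer genes remained higher. This argues only against differences in overall distribution between the deposited arrays. Those differences were small to begin with (uterine array medians of 0.299 to 0.335), and earlier processing steps were not tested. A smaller share of decidual stroma that raised every other cell type alike has values against it. Differences were positive for all 20 natural killer genes, 8 of 9 neutrophil genes and 8 of 13 T and B cell genes. They were negative for 20 of 27 smooth muscle genes and 10 of 18 macrophage genes. Adjusted over the list alone, 13 natural killer and 0 smooth muscle genes were higher. This argues against an equal rise in these lists, and leaves a smaller share with other changes open. Natural killer genes exceeded smooth muscle genes by 0.2425 in mean difference (SE 0.0278 over members), so the lists moved apart on these arrays. That SE treats members as independent, where their estimated correlations were 0.12 and 0.485. It does not measure the spread between arrays. A change in natural killer cells themselves, a delay in implantation or decidualization, and fewer or less differentiated decidual cells stay open, as does an effect of genotype. None of these was tested, since there is 1 time point and no count of cells, so the pattern may be read as reduced or delayed decidualization only as a hypothesis. The share of trophoblast in the sites was not tested either, since that list had fewer than 5 tested genes in the uterus. Tpbpa, a member, averaged 0.378 in uterine controls and 0.0594 in mutants, at background on every mutant array. For the difference between tissues, 4 of 6 members were more negative in the uterus (1 past the threshold) and 2 more positive. Camera did not call the list (adjusted p = 0.124).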

How the results depend on the processing

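The difference limits, the tests with unnamed probe sets and those over genes that pass the filter in both tissues were chosen after the data had been seen. Of the results past their threshold, 1 changed sign under the alternatives run: the interferon list's median in the oviduct was -0.01404 without mutant array 3 and up to 0.09359 without another array. With an unadjusted p under 0.05 and a difference of at least 0.2, 105 oviduct genes, 556 genes for the difference between tissues and 7021 between control tissues passed. With an adjusted p under 0.05 and a difference of at least 0.3, 112 uterine genes passed, 131 for the difference between tissues and 4581 between control tissues. A trended and robust prior variance gave 36 oviduct genes, and all 12 arrays in 1 fit gave 539 uterine genes. The cause of these was not tested, except that stricter limits pass fewer genes by construction. With a correlation estimated per list, camera called 0 lists in the oviduct, 0 in the uterus, 2 for the difference between tissues and 0 between control tissues, with 1, 3, 6 and 8 lists at an unadjusted p under 0.05.

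Leaving out each array in turn, which leaves fewer arrays, gave 0 to 17 oviduct genes, 124 to 348 uterine genes and 156 to 280 genes for the difference between tissues. The lists called ranged from 3 to 7 in the oviduct and from 5 to 11 in the uterus. The uterine Smad4 difference ranged from -0.2221 to -0.1647, and the correlation of mutant effects from 0.02036 to 0.1182. Of the named genes not past the threshold, 10 differences changed sign when an array was left out. In the oviduct the ranges were -0.1179 to 0.000943 for Inha, -0.06757 to 0.009325 for Cnp, -0.01911 to 0.05753 for Rbp4, -0.01837 to 0.0475 for S100b and -0.1709 to 0.006927 for Egr1. In the uterus they were -0.06566 to 0.02181 for Cnp, -0.1086 to 0.009228 for Sema3d, -0.05895 to 0.000492 for Notch3 and -0.01129 to 0.2072 for Zbp1. For the difference between tissues it was -0.09278 to 0.234 for Usp18.

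Within a tissue the values gave no sign that the replicate numbers pair the arrays. The deviations of arrays with one number correlated at 0.042, -0.191 and 0.015 in the oviduct and at -0.02, 0.048 and -0.119 in the uterus. Between tissues, same-numbered mutants correlated at 0.269, 0.241 and 0.258, and arrays with other numbers at -0.158 to -0.093, a hint from the data that the numbers pair the mutant arrays across tissues. Deviations were taken from the mean of each group's 3 arrays, so the negative values follow in part from the positive ones. Same-numbered controls correlated at -0.188, 0.132 and -0.339 and other-numbered ones at -0.208 to 0.395, highest for oviduct array 3 with uterus array 1 (0.395) and oviduct array 1 with uterus array 3 (0.262). The values thus give no sign that the control numbers pair the arrays. Whether control tissues share animals, under the same or other numbers, is open. With the replicate number as a block (within genotype for the comparisons of tissues), 25 oviduct genes, 278 uterine genes, 163 for the difference between tissues and 11083 between control tissues passed, and uterine Smad4 was -0.1874 (adjusted p = 0.0617). The uterine calls of Spink1, Ctsw, Klrd1, Sprr1a and Gzmc then had an adjusted p of 0.109, 0.0941, 0.0609, 0.0523 and 0.0517. Of the 25 oviduct genes 12 were among the 18 called without the block, and Mcpt4, Nptx2, Apod, Cacng4, Astn1 and Cpz then had an adjusted p of 0.0693, 0.0868, 0.104, 0.0508, 0.098 and 0.102. The planned limits on fold were not run, since the scale gives no fold. The level of background limits genes such as Amhr2 in the oviduct.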

Other observations

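The tests of mast cell markers, of adipocyte genes and of neighbouring genes were chosen after the results were seen. Small nucleolar RNAs had a median difference of 0.0647 in the mutant uterus, with 74 of 95 positive, 5 higher past the threshold and 0 lower. In the oviduct the median was 0.0591, with 66 of 87 positive and 0 past the threshold. Both medians stayed positive with quantile normalization (0.0668 and 0.0556) and with median centring (0.0597 and 0.0666). The array medians of 95 such RNAs overlapped between genotypes, at 1.12, 1.36 and 1.23 in uterine controls, 1.39, 1.35 and 1.23 in uterine mutants, 0.678, 0.745 and 0.650 in oviduct controls and 0.843, 0.692 and 0.703 in oviduct mutants. The uterine median difference was 0.0383 without control array 1, 0.0223 without mutant array 1 and 0.111 without mutant array 3. The uterine count past the threshold was 2 without control array 1, 1 without control array 3, 2 without mutant array 1, 3 without mutant array 2 and 17 without mutant array 3. The oviduct median was 0.0312 without control array 3 and 0.0386 without mutant array 3. Immunoglobulin variable genes had a median difference of -0.131 in the oviduct, with 34 of 154 positive, 3 lower past the threshold and 0 higher, and of 0.0363 in the uterus, with 87 of 150 positive, 1 higher and 1 lower. The oviduct median was -0.0369 without mutant array 1 and -0.0774 without control array 3, with 0 genes past the threshold in each case, 5 without control array 2, 2 without mutant array 2 and 6 without mutant array 3. The uterine median ranged from -0.0332 without control array 3 to 0.102 without mutant array 1, so it has no settled sign. These genes spread widely between replicate arrays, with a median SD of 0.292 in the oviduct and 0.264 in the uterus, against 0.0448 and 0.0439 over all genes tested. Their array medians in the oviduct were 0.849, 0.736 and 0.948 in controls and 0.509, 0.723 and 0.914 in mutants.

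Of 15 mast cell markers with a probe set, from a list written after Cpa3, Mcpt4 and Tpsb2 had been seen, 4 were higher in the mutant oviduct past the threshold. Of the 11 others, 3 (Cma1, Hpgds and Mrgprb1) were higher on every mutant array than on every control array, by 0.178 (SE 0.0309), 0.0863 (SE 0.0360) and 0.0892 (SE 0.0318), where 0.55 such markers are expected by chance, but Cma1 and Mrgprb1 lay at background, and Tpsab1, Fcer1a and Ms4a2, also at background, differed by -0.0114, 0.0268 and 0.0185. Hdc, Gata2, Hpgds and Kit, with control levels of 2.63, 2.39, 2.08 and 1.43, are bright enough in the oviduct to hide a small share of mast cells, and other lists hold Hdc and Gata2. Slc45a3, which passed the filter at a dimmer 0.309, differed by only 0.0103 (SE 0.0383). It did not follow the 4 markers past the threshold, but 1 marker does not decide the question. The bound of that test was set with these values known, so more mast cells may explain the pattern but the test does not decide it. More fat carried over with the mesosalpinx is open too, since the 9 adipocyte genes had a mean difference of 0.093 but no call with an estimated correlation (adjusted p = 0.684), as is genotype.

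At an unadjusted p under 0.01 in each tissue, 37 genes stood out, 29 in the same direction and 8 in opposite directions, where 7.68 are expected in each by chance. A linked segment around the floxed or the cre-carrying gene could shift neighbours in both tissues. Of the 28 shared genes other than Smad4 and Amhr2, 1 (Mettl7a1) lay among the 50 tested neighbours on each side of Smad4 or Amhr2, against a median of 0 over 10000 random draws (one-sided permutation p = 0.295). Clusters in other segments were not decided either, with 5 pairs of shared genes within 50 tested genes of each other against a median of 2 (one-sided permutation p = 0.125). Genotype stays open and untested. Tissues taken from the same animals stay open too, since same-numbered arrays of the 2 tissues correlated at 0.241 to 0.269 in mutants and at -0.339 to 0.132 in controls, where other-numbered arrays reached 0.395 and 0.262.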
